A study of Mus musculus with 7 samples.

How the data were processed

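Polyadenylated RNA was measured by sequencing in 7 soft tissue samples of mice, taken next to a 1.5-mm drill hole in the mandible on day 5 after the injury. Per the labels, 4 samples came from WT mice and 3 from mice that lack Il17a and Il17f (IL17KO), the libraries were made with a stranded mRNA kit, and the tissue was muscle and soft callus. The labels call the WT mice littermates of the knockouts. Nothing in the labels says that each library is a separate animal, so p-values measure the spread between these samples.

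The deposited table holds raw read counts per gene and a normalized count signal per gene for each of the 7 libraries. Per the submitters' processing notes, the tools named were bcl2fastq, FastQC, cutadapt, TopHat, HTSeq and DESeq2, and the build was GRCm39; their versions and settings are not given in the sources used here. The deposited normalized signal equals the counts divided by 1 size factor per library. It is given for 19754 of the 49164 gene rows with counts, those with at least 10 counts in total. A further 6250 of the 55414 gene rows are blank in every column, among them T cell receptor and immunoglobulin genes, so receptor segments that mark gamma-delta T cells were not analysed here. The annotation used here was GENCODE's for GRCm38, an older build, so it served only for chromosome names, gene order, gene types and transcript sequences, and no coordinates are given. Of the 15399 tested genes, 15376 were found in it.

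The counts as deposited were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test, two-sided, with TMM normalization, the filterByExpr filter and robust dispersion. The Benjamini-Hochberg adjusted p had to be under 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. Levels are CPM, counts scaled to a common library size, computed on TMM-scaled library sizes, as mean ± SD. The 36 gene lists were fixed before the data were examined and hold 633 entries, of which 626 were found in the table. The 31 lists with at least 5 tested members were tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move 1 way on balance, were alternatives. The mixed form of fry asks whether they change in either direction, without comparing the list with other genes. The mean level of each list per library was also compared by an exact two-sided permutation test over all 35 splits of the 7 libraries into 4 and 3, whose smallest possible p is 0.0286. This permutation test was added after the data were examined. So was a linear model of the mean level of 5 lists on the group, with the muscle level as a covariate or without WT replicate 3, which gives a difference with its SE and 95% interval.

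The genes named were chosen by a rule written before the data were examined. It takes Il17a and Il17f, then, of the genes past the threshold with no overlap of the groups and a mean log2 CPM of at least 0, the 10 largest rises and falls, leaving out predicted genes, genes with -ps for pseudogene in the name and antigen receptor segments. Pseudogenes by annotation alone were not left out. Of each described list it takes up to 4 members with the smallest p. Genes outside the rule are said to be so, and some genes that the rule takes are not reported here.

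Alternatives for the gene and list counts were DESeq2 1.42.0, limma voom with quality weights, RLE normalization, limma-trend on log2 of the deposited normalized values plus 1, no filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, the muscle level as a covariate, an adjusted p under 0.10, and each library left out. Leaving out 2 pairs of libraries was added later. Near-identical copies of tested genes were sought by BLAST among protein-coding GRCm38 transcripts, at 95% identity or more over at least 80% of the length.

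Total counts ran from 18539904 to 26271176 per library, so that a floor of 3 counts is 0.114 to 0.162 CPM. The floors cover counting error only, while the 95% intervals of list levels rest on the spread between libraries. Pairs of libraries of the same group differed by far more than counting noise, with a mean chi-square per gene of 23.1 to 239, so that no library was a repeat deposit. The procedure was tested on simulated data for IL17KO against WT with 15399 genes. At a 4-fold change edgeR recovered 91 of 100 changed genes and DESeq2 93, and at a 2-fold change they recovered 61 and 76. Of 172 edgeR calls in the simulation 16 were unchanged genes, against 54 of 230 for DESeq2, and edgeR called 0 genes where none was changed. Genes were drawn independently in the simulation, so it does not cover variation that genes share between libraries, such as the muscle level.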

Results

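Gene expression was measured in soft tissue beside a drill hole in the mouse mandible on day 5 after the injury. The comparison asks how the tissue differs between mice without interleukins 17A and 17F (IL17KO, 3 libraries) and WT littermates (4 libraries). The study's title concerns IL-17-producing gamma-delta T cells in the healing of such defects. WT replicates 1 to 4 had 21784565, 18539904, 18925451 and 26271176 counts. IL17KO replicates 1 to 3 had 25117173, 24575664 and 25814761.

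The targeted genes were at or below the detection floor in every library. Il17a had 0 counts in all 7 libraries. Il17f had 0 counts in the 4 WT libraries and 1, 1 and 0 counts in IL17KO replicates 1, 2 and 3 (exact binomial p = 0.22). A count of 3 corresponds to 0.114 to 0.162 CPM, so these counts cannot check the genotype labels. Il23r, the receptor for interleukin 23, had at most 3 counts in any library and Ccr6, a chemokine receptor of type 17 cells, at most 4. T cell receptor genes were not analysed here. The 6 tested members of the type 17 gamma-delta list had a median log2 fold change of 0.03, while camera gave the list the opposite sign (adjusted p = 0.969).

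In IL17KO tissue, 24 of 15399 tested genes differed from WT at an edgeR adjusted p under 0.05, 12 higher and 12 lower. Mmrn1 (ENSMUSG00000054641), which encodes the platelet and endothelial protein multimerin 1, had 0 counts in all 4 WT libraries and stood at 3.50 ± 0.62 CPM in IL17KO (SD, n = 3), at least 102-fold above a floor of 3 counts over the WT group. Chil1 (ENSMUSG00000064246), a chitinase-like protein of macrophages and neutrophils, rose from 1.34 ± 0.38 to 7.08 ± 1.79 CPM, and Cadm1 (ENSMUSG00000032076), a cell adhesion molecule, from 8.80 ± 2.38 to 42.2 ± 7.65 CPM. Thy1 (ENSMUSG00000032011), a surface protein of T cells and fibroblasts, fell from 243.3 ± 43.8 to 93.1 ± 19.3 CPM. Ifi208 (ENSMUSG00000066677), of an interferon-inducible family, fell from 2.55 ± 1.02 to 0.151 ± 0.117 CPM.

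**Figure D1:**
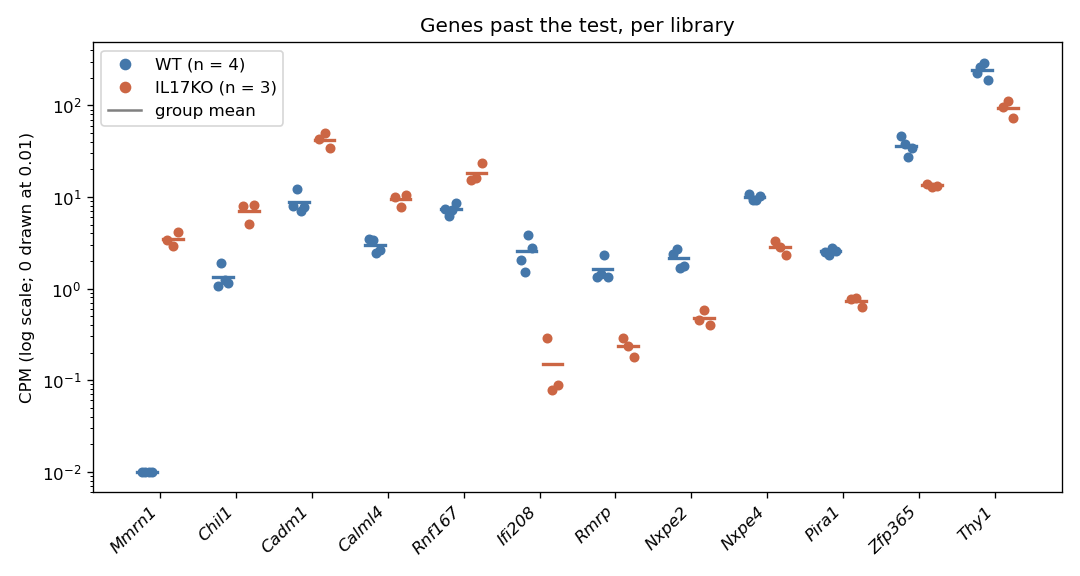
CPM of the 12 named genes past the threshold in each library, on a log axis with a value of 0 drawn at 0.01 (blue, WT, n = 4; orange, IL17KO, n = 3; bars, group means). The groups do not overlap for any of the 12, and Mmrn1 is at 0 in the 4 WT libraries.

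By edgeR, the log2 fold changes were 2.41 ± 0.26 for Chil1 (SE, adjusted p = 0.011), 2.27 ± 0.21 for Cadm1 (adjusted p = 0.00565) and −1.39 ± 0.20 for Thy1 (adjusted p = 0.0463). Calml4 (ENSMUSG00000032246), a calmodulin-like gene, and Rnf167 (ENSMUSG00000040746), a ubiquitin ligase, were higher by 1.66 and 1.31 (adjusted p = 0.0165 and 0.0371). Ifi208 was lower, with a log2 fold change of −4.03 ± 0.52 (adjusted p = 0.0264). Nxpe2 (ENSMUSG00000032028) and Nxpe4 (ENSMUSG00000044229), neighbours on chromosome 9, had −2.13 ± 0.29 and −1.81 ± 0.17 (adjusted p = 0.0371 and 0.00565). Pira1 (ENSMUSG00000081665), a paired immunoglobulin-like receptor gene annotated in GRCm38 as a polymorphic pseudogene, Zfp365 (ENSMUSG00000037855), a zinc finger gene, and a locus named Rmrp (ENSMUSG00000115420) were lower as well, at −1.80, −1.45 and −2.76 (adjusted p = 0.0177, 0.0192 and 0.0264). The groups did not overlap for any of the 24 genes. Among all tested genes 3.89% did not overlap, against 5.71% by chance, and 468 genes had an unadjusted p under 0.05 where chance gives 770.

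Of the 24 genes, 10 have a protein-coding copy that is at least 95% identical over 80% of the length, and their counts are uncertain. The fitted changes of Gm15459 and Gm11942, chosen after their values were seen, were the largest of all, at 9.94 and 9.80 (adjusted p = 1.32e-07 and 2.27e-05). They are 99.7% and 97.4% identical to Hspa8 and Rplp1. Among the named genes, Pira1 and Ifi208 have such a copy. In a count made after the values were seen, 6 of the 24 genes lay on chromosome 9 of the GRCm38 annotation (Cadm1, Calml4, Nxpe1-ps, Nxpe2, Nxpe4 and Thy1), a larger share of its tested genes than of those elsewhere (odds ratio 5.58, Fisher's exact p = 0.00181, adjusted over 22 chromosomes 0.0399). At an unadjusted p under 0.01, 2.64% of the 871 tested chromosome 9 genes differed, against 0.703% elsewhere (Fisher's exact p = 4.78e-07). Neighbouring genes are not independent replicates.

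**Figure D2:**
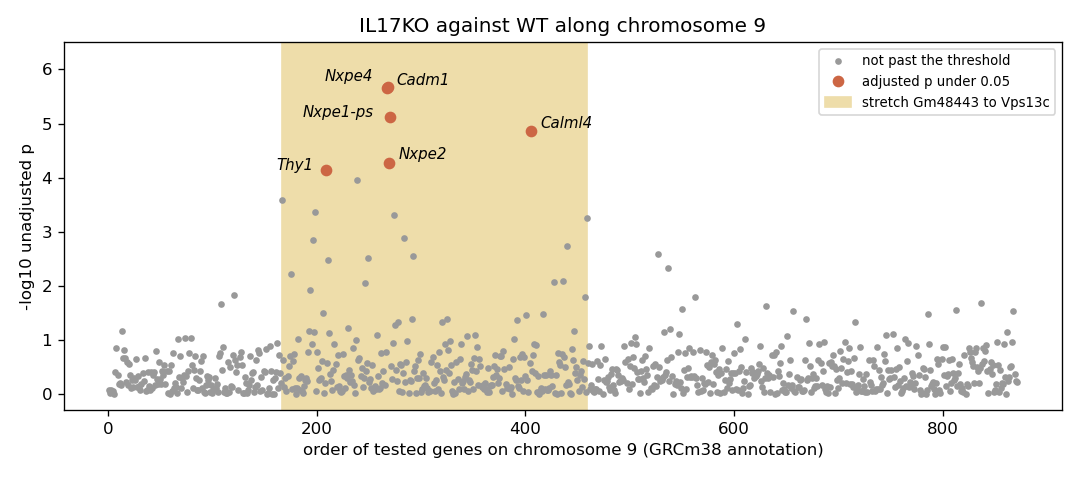
Unadjusted p (as −log10) of the 871 tested genes of chromosome 9 in their order in the GRCm38 annotation. The 6 genes past the threshold (orange) lie within the shaded stretch from Gm48443 to Vps13c, chosen after the values were seen, where 21 of 293 genes had p under 0.01.

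The number of calls was 58 with DESeq2, 64 with limma voom, 42 without a filter and 2 with the replicate block. It fell to 12, 11 and 12 without WT replicates 1, 2 and 4 and to 8, 14 and 14 without IL17KO replicates 1, 2 and 3. Limma voom gave IL17KO replicates 1, 2 and 3 quality weights of 5.31, 0.624 and 0.487. Its IL17KO values therefore rest largely on replicate 1, here and in all limma voom calls below.

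Genes that IL-17 induces in stromal and epithelial cells were mostly at lower values in IL17KO. Of 20 tested members 18 had negative fold changes, with a median of −0.77, and camera at its preset correlation called the list lower (adjusted p = 1.39e-10, and adjusted p = 0.459 with an estimated correlation). By edgeR 0 members passed the test over all genes (8 at an unadjusted p under 0.05), by DESeq2 1 did (Il1b, adjusted p = 0.00939) and by limma voom 0, and 4 were lower by edgeR when adjusted over the list alone. Il1b, an inflammatory cytokine, was at 17.2 ± 6.08 CPM in WT and 5.57 ± 2.65 in IL17KO, and Cxcl1, a neutrophil-attracting chemokine, at 9.90 ± 4.46 and 4.01 ± 1.33. Il6 had a log2 fold change of −0.97 ± 0.28 and Nfkbiz, a regulator of IL-17 target genes, −0.48 ± 0.14. The median of the list was −0.42 with the muscle level as a covariate, −0.36 without WT replicate 3 and −0.43 without WT replicate 3 and IL17KO replicate 3. The mean level of the list overlapped between groups (exact permutation p = 0.114, adjusted over the 31 lists 0.775).

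The neutrophil list was lower by camera as well (13 of 14 members negative, median −0.92, adjusted p = 1.57e-07, and adjusted p = 0.556 with an estimated correlation). S100a8 and S100a9, subunits of calprotectin, had log2 fold changes of −1.08 ± 0.47 and −1.34 ± 0.54, and Mmp9 and Stfa2l1 −1.59 ± 0.61 and −1.94 ± 0.59. By edgeR, DESeq2 and limma voom 0 members passed the test over all genes, with 4, 7 and 9 at an unadjusted p under 0.05, and by edgeR 0 passed when adjusted over the list alone. Mmp9 in WT replicate 3 (215 CPM) stood apart from the other WT libraries. The median was −0.48 with the muscle level as a covariate and −0.50 without WT replicate 3. With WT replicate 3 and IL17KO replicate 3 both left out it was −0.29 and the call ended (adjusted p = 0.172). Its level per library also overlapped between the groups (exact permutation p = 0.171).

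Classical inflammatory cytokines (12 of 15 negative, adjusted p = 5.64e-06) and osteoclast regulators (10 of 11 negative, adjusted p = 6.46e-06) share 4 tested members. With an estimated correlation the adjusted p was 0.459 for each. By edgeR 0 members passed the test over all genes (5 and 4 at an unadjusted p under 0.05), and 3 of each were lower when adjusted over the list alone. Over all genes DESeq2 called Il1b and Ptgs2 lower and limma voom Ptgs2. With the muscle level as a covariate their medians moved from −0.43 to −0.30 and from −0.52 to −0.27. The median of the osteoclast regulators was −0.28 without WT replicate 3, −0.30 without IL17KO replicate 3 and −0.15 without both, where the call ended (adjusted p = 0.22). Ptgs2, the inducible cyclooxygenase, was at 22.3 ± 5.34 CPM in WT and 11.3 ± 1.76 in IL17KO, and Il1a and Il11 had log2 fold changes of −1.26 ± 0.43 and −0.91 ± 0.39.

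Of the 31 tested lists, antigen presentation genes alone had a level that did not overlap between the groups. By chance 5.71% of lists would not overlap, so such a list among 31 is no more than chance gives. Of 15 tested members of the dendritic cell and MHC class II list 11 were negative (median −0.41, camera adjusted p = 4.93e-09, and adjusted p = 0.399 with an estimated correlation), and 4 were lower adjusted over the list alone. Over all genes edgeR called 0 of them (4 at an unadjusted p under 0.05), while DESeq2 and limma voom each called 4 lower, Cd74, H2-Aa, H2-Ab1 and H2-Eb1. The limma voom calls rest largely on IL17KO replicate 1, by its weight. H2-Aa was at 82.5 ± 9.37 CPM in WT and 48.1 ± 6.11 in IL17KO, and H2-Ab1 at 135.5 ± 9.16 and 78.6 ± 13.8. H2-Eb1 and Cd74, the class II invariant chain, had log2 fold changes of −0.75 ± 0.15 and −0.70 ± 0.16. The median was −0.29 with the muscle level as a covariate and −0.26 without WT replicate 3 and IL17KO replicate 3. The exact permutation p of the list's level was 0.0571 (adjusted 0.775).

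**Figure D3:**
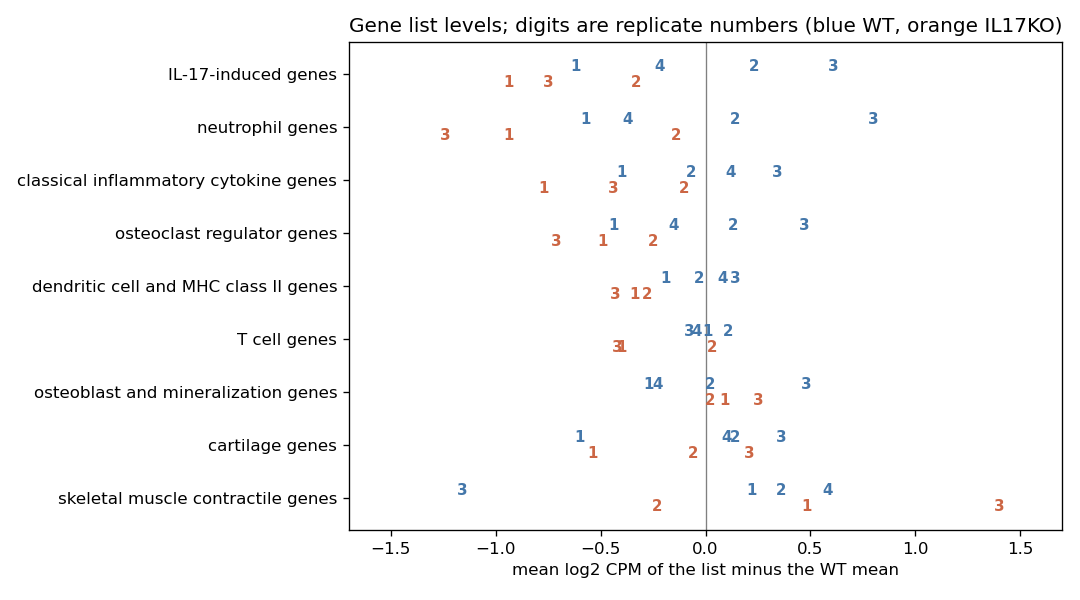
Mean log2 CPM of 9 gene lists in each library relative to the WT mean, with digits for replicate numbers (blue, WT; orange, IL17KO). For the dendritic cell and MHC class II list the IL17KO libraries lie between −0.43 and −0.28 and the WT libraries between −0.19 and 0.14, while the groups overlap for the other lists drawn.

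The T cell list was called lower (4 of 8 tested members negative, adjusted p = 0.0169, and adjusted p = 0.459 with an estimated correlation), with a median of −0.02 and a mean of −0.24. Thy1, which fibroblasts also express, was its only member past the threshold, while Lck, Cd5 and Cd28 had log2 fold changes of −0.59 ± 0.37, −0.44 ± 0.38 and 0.23 ± 0.30. By edgeR Thy1 was also the only member at an unadjusted p under 0.05, and it lies in the chromosome 9 stretch from Gm48443 to Vps13c. The list was not tested without Thy1, so its call cannot be read as a shift of T cell genes in general. Without WT replicate 2 the adjusted p of this list was 0.0557 and its median 0.03, and without IL17KO replicates 1 and 2 in turn the median was 0.10 and −0.36.

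Bone and cartilage genes were not separated by the test. Of 18 osteoblast and mineralization genes 11 were positive (median 0.14, adjusted p = 0.62), and Phex had a log2 fold change of −0.42 ± 0.40 by edgeR and 0.08 by limma voom. Of 14 cartilage genes 10 were negative (median −0.23, adjusted p = 0.225), with Col2a1 at 0.949 ± 0.189 CPM in WT and 0.429 ± 0.159 in IL17KO. Without WT replicate 3 the osteoblast list was higher (adjusted p = 0.0133, and 0.0242 with IL17KO replicate 3 left out too), while without IL17KO replicate 3 its median was −0.03. Without WT replicates 1 and 4 in turn camera gave the osteoblast list the opposite sign (adjusted p = 0.959 and 0.91). Without WT replicate 1 the cartilage list was lower (median −0.40, adjusted p = 0.0274). The cartilage median was 0.01 without WT replicate 3 (6 of 14 negative), −0.06 without WT replicate 4, and −0.02 and −0.46 without IL17KO replicates 1 and 3. Osteoclast genes were lower by camera (14 of 15 negative, adjusted p = 0.0171, and adjusted p = 0.723 with an estimated correlation), a call that ended without WT replicate 3 or IL17KO replicate 3. With the muscle level as a covariate their median moved from −0.27 to −0.05 (adjusted p = 0.934).

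Skeletal muscle contractile genes were called higher in IL17KO (24 of 25 positive, median 0.61, adjusted p = 4.21e-05, and adjusted p = 0.723 with an estimated correlation), and oxidative phosphorylation genes too (21 of 21 positive, adjusted p = 0.0034, and adjusted p = 0.723 with an estimated correlation). Ryr1, the calcium release channel of muscle, was at 1120 ± 452 CPM in WT and 2250 ± 1440 in IL17KO, and Myh7, the slow myosin, at 18.0 ± 3.23 and 12.3 ± 1.28. Relative to the WT mean, the muscle level ran from −1.16 (WT replicate 3) to 0.58 in WT and from −0.23 to 1.40 (IL17KO replicate 3) in IL17KO (mean log2 CPM). The muscle call ended without WT replicate 3 or IL17KO replicate 3 (adjusted p up to 0.694), and so did the oxidative phosphorylation call (up to 0.642). Without IL17KO replicate 3 the muscle median went from 0.61 to −0.01 (13 of 25 negative) and the oxidative phosphorylation median from 0.22 to −0.06 (17 of 21 negative), and without WT replicate 3 they were 0.35 and 0.13. These 2 libraries were the ends of the first principal component, which held 50.1% of the variance. With both left out, the muscle and oxidative phosphorylation lists were called lower (adjusted p = 7.25e-05 and 0.000294).

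The further lists past the threshold were lower: type I interferon response (21 of 21 negative, adjusted p = 0.000863), interferon-gamma response (17 of 19, 0.00226), proliferation (23 of 24, 0.00975), matrix protease (12 of 15, 0.0171) and fibroblast and matrix genes (16 of 22, 0.0295). Their adjusted p was 0.723 with an estimated correlation in each case. With the muscle level as a covariate none of these 5 calls held, and the medians moved from −0.28 to −0.06, from −0.21 to −0.08, from −0.15 to 0.05, from −0.21 to −0.03 and from −0.07 to 0.05, in the same order. The interferon calls ended without WT replicate 3 (adjusted p = 0.316 and 0.138) or IL17KO replicate 1 (0.424 and 0.261), and without WT replicate 3 and IL17KO replicate 3 together (0.924 and 0.54). The proliferation and fibroblast calls ended without WT replicate 3 or IL17KO replicate 3 (adjusted p up to 0.552 and 0.97), and the matrix protease call without either of these or WT replicate 2 (up to 0.316). Without WT replicate 3 the 5 medians were −0.06, −0.08, −0.01, −0.06 and 0.04, and without IL17KO replicate 3 those of the last 3 were 0.04, −0.11 and 0.06. In all, 14 of 31 lists passed camera with the preset correlation, 12 lower and 2 higher. With an estimated correlation 0 passed, and 2 had an unadjusted p under 0.05 (MHC class II and T cell genes). With fry 0 passed, and 1 had an unadjusted p under 0.05 (MHC class II). With the mixed form of fry 2 passed, T cell and MHC class II genes (adjusted p = 0.0355 for each), and 4 had an unadjusted p under 0.05. In the T cell list Thy1 alone had an unadjusted p under 0.05 by edgeR, so these T cell results may rest on that gene.

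Alternatively activated macrophage genes went both ways (6 of 13 positive), and 2 were higher adjusted over the list alone, Cd163 and Lyve1, with log2 fold changes of 0.92 ± 0.22 and 0.85 ± 0.23. Over all genes edgeR and DESeq2 called 0 of these 13 (2 and 3 at an unadjusted p under 0.05), and limma voom called Cd163 higher (adjusted p = 0.0343). For the other lists the camera adjusted p was 0.0888 for monocyte and macrophage genes (14 of 20 negative), 0.261 for alternatively activated macrophage genes, 0.0552 for red blood cell genes, 0.092 for muscle regeneration genes and 0.149 for mast cell and eosinophil genes. It was 0.184 for skeletal progenitor and periosteum genes, 0.229 for BMP, TGF-beta and Wnt genes, 0.315 for endothelial genes, 0.48 for Schwann cell genes and 0.483 for B and plasma cell genes. It was 0.59 for adipocyte genes and for immediate early and heat shock genes, 0.764 for pericyte and smooth muscle genes and 0.967 for hypoxia and glycolysis genes. Some of these lists passed with 1 library left out. Without WT replicate 1 they were monocyte and macrophage (lower, adjusted p = 0.000592), red blood cell (lower, 0.000156), adipocyte (lower, 0.00874) and muscle regeneration genes (higher, 0.000317). Without WT replicate 3 they were alternatively activated macrophage (higher, 0.0197), mast cell and eosinophil (higher, 0.00818) and Schwann cell genes (lower, 0.00721), and without WT replicate 4 red blood cell genes (lower, 0.0209). Without IL17KO replicates 1 and 2 in turn they were red blood cell genes (lower, 2.13e-05) and monocyte and macrophage genes (lower, 0.0195). Without IL17KO replicate 3 they were muscle regeneration (higher, 0.00485), Schwann cell (lower, 0.0149) and immediate early genes (lower, 0.0468). For adipocyte genes the median (0.08) and the mean (−0.53) differed in sign. Lists of NK cell, keratinocyte, salivary gland, tooth and sex-linked genes had fewer than 5 tested members. Tooth enamel transcripts were found in WT replicates 2 and 4, with 428 and 1116 counts of Amelx against 0 in the other 5 libraries, and without these 2 libraries 4 genes were called.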

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

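The tests of near-identical copies, of the chromosome 9 stretch, of muscle level, of WT replicate 3 and of Y-linked transcripts were chosen after the results were seen, and the counts over other splits of the libraries were set beforehand. Of 91 values looked at in the 4 WT libraries, 8 had a library far from the others, where chance gives about 1 in 20 for independent, normally distributed values. These values are not independent of each other. Bpifa2, Amelx, Ddx3y, Eif2s3y, Kdm5d and Uty were also put in the set individually, so the 2 rates cannot be compared strictly. WT replicate 3 stood apart for Mmp9 (215 CPM against 41.5 to 65.0), Il1a (1.54 against 0.736 to 0.816), Col11a1 (209 against 73.0 to 80.1), Ttn (1170 against 2770 to 3050) and the Rmrp locus (2.35 against 1.33 to 1.46). WT replicate 2 stood apart for Cadm1 (12.3 CPM against 7.10 to 7.91), for Bpifa2, a salivary gland gene (20 CPM against 0), and for the mean log2 CPM of sex-linked genes (2.61 against 4.99 to 5.44).

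The count of differing genes stood out from other groupings of the same libraries. The real split gave 24 genes, and the highest of the other 34 splits gave 2, so that 1 of 35 splits gave as many. This is the smallest share that 35 splits can give, so the test argues against chance only to this limit and cannot exclude it. Nor does the test separate the genotype from anything else that the libraries of a group share. The count of lists did not stand out. The real split gave 14 lists, 17 of the 35 splits gave at least as many, another split gave 22, and the lowest count was 4, so that chance cannot be excluded for the number of lists past camera with the preset correlation.

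The first pattern is the set of 6 genes called higher in IL17KO that have a near-identical protein-coding copy. Reads shared between copies are a candidate explanation. In 5 of 5 families the coding copy was lower in IL17KO and the summed CPM was closer to equal. Tdg was at 40.8 against 24.9 CPM alone, and at 40.9 against 37.2 with its copies Tdg-ps and Tdg-ps2. The Rnf26 family changed sign, from −1.05 for the coding copy to 0.77 when summed (log2 scale). The copies were picked as higher in IL17KO, so adding them raises the IL17KO sum by construction. With a lower coding copy, the sum could fail only by overshooting, so the sums are weak support. Whether sequence differs between the groups was not tested on reads, and a stretch of chromosome 9 from another strain may be the source for part of these genes, since the copies of Tdg-ps, Tdg-ps2 and Gm28438 lie outside it. Among annotated pseudogenes, with the best-scoring copy, 1 of 5 called genes against 0 of 76 others had its copy in the stretch (Fisher's exact p = 0.0617). A definition chosen after that result took all tested genes off chromosome 9. With the most abundant copy 3 of 6 against 0 of 250 had it in the stretch (Fisher's exact p = 7.24e-06). With the best-scoring copy 2 of 6 did (Fisher's exact p = 0.00046), so that the 3 definitions gave different answers about the stretch. Gm15459 went from 0.267 CPM in WT to 272 in IL17KO, while its sum with Hspa8 was 1360 and 1400 CPM. For this family the near-equal sums argue against a higher total in IL17KO. Loss of IL-17 and a difference in background go with the same groups, and these counts alone do not tell them apart.

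The second pattern is the lower level of the IL-17-induced, neutrophil, inflammatory cytokine, osteoclast regulator and MHC class II lists. For the MHC class II list, muscle content and WT replicate 3 as the whole source are argued against. The difference of its mean log2 CPM (IL17KO minus WT) was −0.35 ± 0.09 (SE) in all libraries. It was −0.30 ± 0.09 both with the muscle level as a covariate and without WT replicate 3 (95% interval −0.55 to −0.05 in each). These intervals are not adjusted for the choice of this list among 31. Chance (exact permutation p = 0.0571, adjusted 0.775), loss of IL-17 and a difference in background stay open. For the other 4 lists, in the order above, the differences moved from −0.68, −0.78, −0.44 and −0.48 to −0.47, −0.41, −0.32 and −0.30 with the covariate and to −0.47, −0.51, −0.32 and −0.32 without that library. Their intervals included 0 with all libraries as well, so that chance stays open for these 4 lists. Muscle content or WT replicate 3 may also be the source and cannot be told apart from loss of IL-17. By camera all 5 lists remained past the threshold under both settings, with medians that without WT replicate 3 moved from −0.77 to −0.36 (IL-17-induced), −0.92 to −0.50 (neutrophil), −0.43 to −0.45 (inflammatory cytokine), −0.52 to −0.28 (osteoclast regulator) and −0.41 to −0.36 (MHC class II), but camera with the preset correlation called at least 4 lists in every split, so these calls decide nothing here.

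The third pattern is the low level of Y-linked transcripts in WT replicate 2, at 0.146 (Ddx3y), 0.108 (Eif2s3y), 0.153 (Kdm5d) and 0.242 (Uty) of the median of the other libraries. Female tissue in this library is argued against by 0 counts of Xist, which female cells express strongly, although with at most 1 count in any library none shows that it would be counted. The Y-linked ratios are of CPM, which already scales for depth, so a shallower library is no source of them by construction. Its total count was 0.746 of the median of the others. X-linked Eif2s3x and Kdm6a were at 0.984 and 1.04 in CPM. Loss of the Y chromosome from part of the cells stays open and was not tested.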

How the results depend on the processing

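Leaving out 2 pairs of libraries was chosen after seeing the data, and the other alternatives were set before. The cause of each change was not tested, except that fewer libraries give less power. All 24 genes were also called by DESeq2, limma voom, RLE, no filter and the muscle covariate. Of the 12 named genes past the threshold, 0 kept their call with the replicate block, 1 without the libraries with enamel transcripts, and 2 to 10 with 1 library left out. The count was 24 with RLE, 21 with the stricter filter, 27 on the deposited normalized values, 35 with the muscle covariate, 30 without the libraries at the ends of component 1 and 29 at an adjusted p under 0.10. It was 58 (27 higher, 31 lower) with DESeq2, 64 (23 and 41) with limma voom and 42 (21 and 21) with no filter. Without the 2 libraries with enamel transcripts it was 4 (4 higher, 0 lower by edgeR, with 444 genes at an unadjusted p under 0.05). With 1 library left out it ran from 8 to 21, with 7 to 11 higher and 1 to 11 lower. With the replicate block it was 2 (2 higher, 0 lower, with 268 genes at an unadjusted p under 0.05). The numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.143, −0.298 and −0.56. The list count of 14 was 8 with the muscle covariate, 0 with an estimated correlation, 0 with fry (2 with its mixed form), 16 with the block, and 10 to 19 with 1 library left out. The muscle covariate is the mean level of the muscle contractile list, so the loss of that list's call was fixed in advance. The IL-17-induced, neutrophil, MHC class II, inflammatory cytokine and osteoclast regulator lists kept their call with each library left out, with adjusted p up to 0.00154. Without WT replicate 3 their medians moved from −0.77 to −0.36, −0.92 to −0.50, −0.41 to −0.36, −0.43 to −0.45 and −0.52 to −0.28, in the same order. Without the libraries at the ends of component 1 they were −0.43, −0.29, −0.26, −0.34 and −0.15, and the neutrophil, osteoclast regulator and both interferon calls ended (adjusted p = 0.172, 0.22, 0.924 and 0.54). Osteoblast genes were then called higher (0.0242), and adipocyte, Schwann cell and immediate early genes lower (0.0124, 3.34e-08 and 0.000822). Without the libraries with enamel transcripts, progenitor genes were called lower (0.0197).

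Lists that changed direction with a setting had these adjusted p-values in the new direction. With the stricter filter they were 0.978 (B cell), 0.223 (adipocyte) and 0.917 (type 17). With fry they were 0.992 (adipocyte, type 17), and with no filter 0.872 (type 17). With the replicate block they were 0.979 (Schwann cell), 0.862 (adipocyte) and 0.809 (type 17). With the muscle covariate they were 0.934 (fibroblast), 0.936 (monocyte and muscle), 0.302 (oxidative phosphorylation) and 0.378 (proliferation). For the muscle list this says nothing, since the covariate is its own mean level. Without the libraries at the ends of component 1 they were 0.924 (B cell), 0.54 (BMP), 0.518 (endothelial), 0.0242 (fibroblast), 0.636 (protease), 0.22 (monocyte), 0.711 (osteoclast), 0.000294 (oxidative phosphorylation), 0.833 (pericyte), 0.000193 (proliferation), 0.881 (red blood cell), 7.25e-05 (muscle) and 0.373 (progenitor). Without the libraries with enamel transcripts they were 0.389 (Schwann cell and immediate early), 0.00241 (adipocyte), 0.542 (osteoblast) and 0.655 (type 17). For lists that changed direction with at least 1 library left out, the adjusted p over all 7 libraries left out in turn, in either direction, ranged over 0.0862 to 0.824 (endothelial), 0.206 to 0.894 (hypoxia), 1.26e-07 to 0.642 (oxidative phosphorylation), 0.514 to 0.949 (pericyte), 5.53e-08 to 0.552 (proliferation), 0.0682 to 0.994 (progenitor), 0.605 to 0.97 (type 17), 0.00181 to 0.97 (fibroblast), 0.0468 to 0.793 (immediate early), 0.00874 to 0.853 (adipocyte), 0.0133 to 0.959 (osteoblast) and 0.00721 to 0.978 (Schwann cell). In the new direction the lowest of these was 0.104 (adipocyte). Some named genes not past the threshold changed sign, to log2 fold changes of 0.08 (Phex, limma voom), 0.00 (Cd28, muscle covariate), −0.09 (Ank) and −0.07 (Cd28), both without the ends of component 1, and −0.04 (Dlx6, without enamel libraries). Ank ran from −0.10 to 0.38 with 1 library left out. Genes with 3 counts or fewer, Il17a and Il17f among them, lie at the limit of the depth.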

Other observations

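The tests in this part were chosen after the values were seen. The genes named first were picked because of their values, and none passed the edgeR threshold. Cd163 was at 12.5 ± 3.22 CPM in WT and 23.7 ± 4.60 in IL17KO, Lyve1 at 6.53 ± 1.17 and 11.8 ± 3.56, Cbr2 at 15.8 ± 3.25 and 25.5 ± 1.27, and Cd5l at 2.05 ± 0.22 and 3.79 ± 0.44 (mean ± SD, n = 4 and 3). Limma voom, which gave IL17KO replicate 1 most weight, called Cd163 and Cbr2 (adjusted p = 0.0343 and 0.0147), and DESeq2 called none of the 4. Fcgr4 (13.9 ± 3.06 and 7.93 ± 1.22), Clec4a1 (34.2 ± 3.76 and 23.0 ± 2.32) and Adgre4 (2.50 ± 0.62 and 0.945 ± 0.181) were at lower values in IL17KO. Limma voom called these 3 (adjusted p = 0.0388, 0.0257 and 0.0347) and DESeq2 Adgre4 (0.0137). A hypothesis is that resident macrophages may make up more of the IL17KO tissue. Of 13 further tested resident macrophage genes, listed before they were tested as a set but after values of some had been seen, 10 were positive with a median of 0.20 (SD 0.43), while Mrc1, Igf1 and Timd4 were at −0.22, −0.17 and −0.02. Camera gave p = 0.0469 at the preset correlation and p = 0.234 with an estimated correlation, and the exact permutation p was 0.286, so the hypothesis stays undecided.

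Of 3 further genes picked because of their values, none passed the edgeR threshold. F3, the tissue factor that starts coagulation, was at 21.2 ± 2.43 and 13.4 ± 1.37 CPM, Il33, an alarmin, at 31.5 ± 3.46 and 20.7 ± 4.87, and Hbegf, a growth factor, at 11.2 ± 1.65 and 7.93 ± 0.72. All 3 were at lower values in IL17KO with no overlap of the groups. DESeq2 called F3 (adjusted p = 0.0242), and limma voom called F3 and Il33 (adjusted p = 0.0382 for each).

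Mmrn1, with 83, 75 and 94 counts in the IL17KO libraries, was among 5 genes that had 0 counts in all 4 WT libraries and at least 10 in each IL17KO library. The highest of the other splits had 0 such genes. Bpifb1 had 38, 44 and 15 counts in the IL17KO libraries. A candidate explanation is a deletion or other difference present in all mice of one group. Loss of IL-17 and such a difference go with the same groups, and the labels used here call the WT mice littermates.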
